A study of Mus musculus with 9 samples.

How the data were processed

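Transcript levels were measured in metaphase II mouse oocytes from females of 3 ages with 1-colour Agilent whole-genome microarrays. Per the labels, the females were B6C3F1 hybrids of a C57Bl/6J and a C3H/HeN parent, called prepubertal at 3 weeks, mature at 8 ± 1 weeks and climacteric (near the end of reproductive life) at 58 ± 10 weeks. The growth protocol gives 52 weeks for the oldest group, and which of these ages applies to the arrays was not settled. Each of the 9 arrays carried RNA from a pool of 20 oocytes, with 3 pools per age. Females received 10 IU of pregnant mare serum gonadotropin and, 48 h later, 10 IU of human chorionic gonadotropin, and oocytes were taken from the oviduct 14 h after that and freed of cumulus cells. One label describes the oocytes as zona-enclosed and another describes removal of the zona pellucida with lysis in a detergent buffer, so the state of the zona in the RNA samples is not certain. Per the labels' protocols, RNA was isolated on RNeasy Micro columns without DNase treatment, amplified in 2 rounds with a RiboAmp HS Plus kit, and 3 µg of the product was labelled with Cy3. Amplification over 2 rounds can change the relative level of transcripts and adds spread between pools.

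The deposited scanner files hold an intensity for each spot in linear fluorescence units. Per the file headers, spots were read with Feature Extraction 9.5.1.1 (the submitters' processing notes give version 9.5), with a spatial trend and a multiplicative trend removed, no further global background correction, and a surrogate value in place of signals too near background. The array design carried 39429 probes other than controls, 399 of them in 10 spots each. Probe positions in the files refer to mouse build mm9 (NCBI37). The deposited value table holds a log2 value for each probe and array. Its scale was established by setting each column against the same array's mean spot intensity: Pearson's r across probes was 0.999 on the array where it was lowest, and the sorted columns differed by at most 0.0491, which is the form that log2 mean intensity takes after quantile normalization. The authors' normalization step is not stated in the sources used here, and the table's column medians were 8.03 to 8.04. It was used only as an alternative.

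Main values were log2 of the processed signal minus the 75th percentile of that array over all probes other than controls. A level of 0 is therefore the array's 75th percentile, and a difference of 1 is a 2-fold change. Spots marked as outliers by the software were left out, which was 0.195% to 0.621% of spots per array, and saturated spots were kept (at most 4 probes on an array). Repeated spots of a probe were averaged. A probe was tested if it was well above background on at least 3 of the 9 arrays and measured on at least 2 arrays of each age, which left 30451 probes. Where a gene had several probes, the probe with the highest mean over the 9 arrays stood for it. That gave 25089 genes or probes without a gene name, of which 19331 had a symbol. Symbols were updated through accessions and synonyms in a RefSeq gene table of GRCm38.p6, used for names only: 26581 probes matched it, 4818 kept the symbol of the array file, and 8030 had no symbol. No annotation of exons or untranslated regions on mm9 was used here.

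Array precision is limited by their number, 3 per age, and by signal over background. The share of probes well above background was 73.4%, 68.0% and 72.9% on prepubertal arrays 1 to 3, 70.9%, 76.8% and 76.6% on mature arrays 1 to 3, and 73.8%, 77.5% and 66.8% on climacteric arrays 1 to 3. A probe not well above background on any array of a group has only a bound there. Its fold is then given as at least the brighter group's mean over the mean of, per dim array, the higher of the probe's own level and the lowest level of any probe well above background.

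Groups were compared with limma, with 1 mean per age fitted to all 9 arrays and moderated (empirical Bayes) statistics, two-sided, and Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p of 0.05. The 3 pairwise comparisons were made, and a moderated F test covered the 3 ages together. The fit had 6 residual degrees of freedom and 2.45 from the prior. The labels do not say whether the pools of an age came from different females, so p-values measure the spread between these pools, which may be partly technical.

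Gene lists were fixed before the data were examined. There were 26 lists of genes by function (oocyte identity and maternal-effect genes; cohesin; spindle checkpoint and kinetochore; meiotic cell cycle; oxidative phosphorylation; mitochondrial ribosome; cytosolic ribosome; proteasome; translation factors; antioxidant defence; DNA repair; DNA methylation and chromatin; histones; chaperones; unfolded protein response; glycolysis; citric acid cycle; cholesterol; maternal mRNA storage and decay; apoptosis; telomeres; nutrient sensing; autophagy; mitochondrial dynamics; sperm binding and egg activation; oocyte-biased multigene families) and 6 lists of markers of other cells (cumulus and granulosa; theca and stroma; oviduct epithelium; erythroid; leukocyte; endothelium). Each was tested with limma's camera at a preset correlation between genes of 0.01, which compares the members with all other genes, and adjusted over the 32 lists of a comparison. Camera with an estimated correlation and the rotation test fry stood beside it. Lists past the threshold for prepubertal against mature or climacteric against prepubertal were also set against 10000 random lists of the same size, matched on mean expression, and the central 95% of their medians was taken as the range. The random genes were drawn independently, while members of a real list can be correlated, so this range can be too narrow. Fry asks whether a list's members move one way on balance, without reference to other genes. Named genes were also chosen by a rule fixed beforehand. It took the called genes of at least 2-fold change whose groups did not overlap and that had a proper symbol: the 8 largest rises and 8 largest falls against the mature group and the 5 and 5 between the youngest and oldest group. It added up to 4 called members, or else up to 2 members with the largest change, of each list described, and a panel of 14 oocyte genes. The other called genes are named as part of small counts, after their values were seen.

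Slide was tested as a batch. Slide 1 held the 3 prepubertal arrays and mature array 1, slide 2 held mature arrays 2 and 3 and climacteric arrays 1 and 2, and slide 3 held climacteric array 3. With slide as a fixed block, prepubertal against mature therefore rests on the 3 prepubertal arrays and mature array 1. That is the same difference as within slide 1. Climacteric against mature then rests on the arrays of slide 2, as within that slide, and climacteric against prepubertal combines both differences. The blocked fits and the fits within a slide are thus not separate checks. All arrays shared 1 scan day, so scan date was not used as a block. The alternatives chosen beforehand were normexp background correction with an offset of 50, quantile normalization, a percentile over probes above background on all arrays, no filter on dim probes or a filter at all 9 arrays, other rules for genes with several probes, the deposited table, a fit to only the 6 arrays compared, a trended robust prior, a 2-fold minimum, the replicate number or the slide as a block, and leaving out each array in turn. Cyclic loess normalization, slide as a random block, fits within slide 1 or 2, and a fit without the 2 arrays with the lowest share of probes above background (prepubertal 2 and climacteric 3) were added after the data were seen.

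The test was checked on simulated data, 10 draws with 200 genes changed among 24983. For prepubertal against mature, 27.3% of genes changed 2-fold were recovered, 69.6% at 4-fold and 84.2% at 8-fold, with 6.2 false calls per draw. For climacteric against mature the shares were 23.7%, 69.6% and 85.5%, with 7.3 false calls per draw. A shift of 0.3 log2 put on the oxidative phosphorylation list was found by camera in 10 of 10 draws for climacteric against mature, with 0 other lists called. Genes were drawn independently of each other and without a slide effect, whereas the estimated correlation within this list was 0.23 in the real data. The draws therefore cannot show how often camera finds or wrongly calls a list here. For single genes, the shares recovered and the false calls depend on the 200 genes changed. They hold for such draws and are not the rates of the real comparisons. Software was R 4.3.3 and limma 3.58.1, with statmod 1.5.0 and the data.table package, version 1.17.8.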

Results

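Transcript levels were compared in ovulated mouse oocytes, arrested at metaphase II after hormone priming, from females that were prepubertal (3 weeks), mature (8 weeks) or climacteric (58 weeks). Each age was represented by 3 pools of 20 oocytes, and each pool was hybridized to 1 array. The series was described as a study of the effect of maternal age on oocytes. Between 66.8% and 77.5% of probes were well above background on an array, and 25089 genes or unnamed probes were tested. Over genes, arrays of the same age correlated at a mean r of 0.972 (prepubertal), 0.979 (mature) and 0.970 (climacteric). Between ages the mean r was 0.972 for prepubertal with mature, 0.971 for mature with climacteric and 0.962 for prepubertal with climacteric arrays. Prepubertal and climacteric arrays were thus no closer to their own age than to mature arrays. The first principal component held 26.3% of the variance and ran from the prepubertal arrays through the mature to the climacteric ones. Slides were not balanced over ages: the 3 prepubertal arrays and mature array 1 shared slide 1, and 4 of the other arrays shared slide 2.

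**Figure D1:**
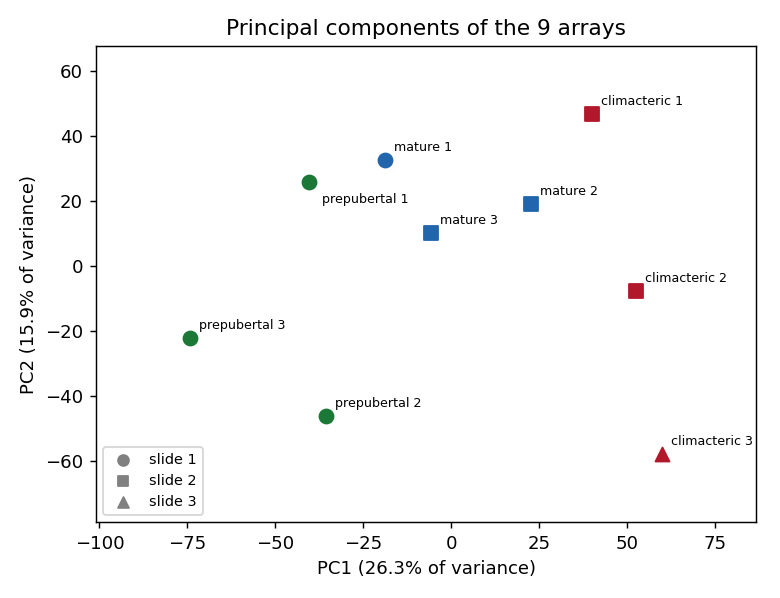
Principal components 1 and 2 of log2 levels over genes measured on all 9 arrays, in arbitrary units, with 1 point per array, coloured by age (green prepubertal, blue mature, red climacteric) and shaped by slide. The prepubertal arrays lie between -74.2 and -35.7 on component 1 and the climacteric arrays between 40.1 and 59.9, while the mature arrays lie between -18.9 and 22.5.

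Prepubertal oocytes were set against mature oocytes to ask how the transcripts of eggs ovulated before puberty differ from those of adult females. Of 14 genes that differed, 9 were vomeronasal type 1 receptors (Vmn1r genes, known as pheromone receptors of the nose), and all 9 fell in prepubertal oocytes, by 1.35 to 2.35 on the log2 scale. Vmn1r181 had a level of -4.16 ± 0.15 in prepubertal and -1.81 ± 0.27 in mature oocytes (SD, n = 3), a 5.12-fold difference. Vmn1r183 went from 1.94 ± 0.07 in mature to -0.06 ± 0.28 in prepubertal oocytes, and Vmn1r178, Vmn1r122, Vmn1r139, Vmn1r151, Vmn1r131 and Vmn1r124 fell by 3.56 to 4.16-fold. Plgrkt, which encodes a plasminogen receptor, fell 3.47-fold and Srp68, a subunit of the signal recognition particle, 3.02-fold. Defb41, a beta-defensin, rose 2.86-fold, from 2.01 ± 0.11 to 3.53 ± 0.22.

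The probes of the 9 Vmn1r genes lie on chromosome 7 of mm9, between 20707065 and 24840710, in a block of closely related receptor genes. Which member of the family each probe reads is uncertain: 8 of the 9 have a probe at least 80% identical in sequence to that of another called member. The remaining 1, Vmn1r240, fell 2.55-fold. A second probe of Vmn1r183, also above background on 9 arrays, differed by only -0.17, and that of Vmn1r178 by -0.23. Altogether 98 Vmn1r genes were measured, and uncalled ones within the same block went both ways. Vmn1r132 (-1.86) and Vmn1r148 (-1.74) fell, with probes 53.3% and 50% identical to the nearest called one, while Vmn1r157 (0.23) and Vmn1r101 (0.32) did not. On chromosome 13, Vmn1r217 (-2.66) and Vmn1r219 (-2.11) were also lower without being called (limma adjusted p = 0.573 and 0.389). The median of the 9 stayed negative under every normalization tried, between -1.64 (deposited table) and -2.01 (percentile over probes above background). The 9 were chosen for being lower on these same arrays, so that sign was largely fixed in advance.

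Lpxn (leupaxin, a focal adhesion adaptor) and the olfactory receptor Olfr1322 also rose in prepubertal oocytes. Their probes were not well above background on any mature array, so they were at least 2.00-fold and at least 1.78-fold higher. The Plgrkt probe lies on chromosome 19 at 29423415 to 29423474, the Srp68 probe on chromosome 11 at 116106502 to 116106561, the Defb41 probe on chromosome 1 at 18241243 to 18241302 and the Lpxn probe on chromosome 19 at 12908221 to 12908280. A dimmer second probe of Defb41, above background on 3 arrays, differed in the opposite direction, by -1.17.

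The 14 genes passed limma's test at an adjusted p between 0.0306 and 0.0443, with SEs of 0.14 to 0.27 for log2 differences, and all 3 arrays of one age lay outside the range of the other. At an unadjusted p under 0.05 there were 2826 genes, where 1254 would come by chance, and the groups did not overlap for 18.4% of genes, where chance gives 10%. By scaling, the split of 3 higher and 11 lower became 1 and 12 with quantile normalization, 1 and 10 with normexp, and 1 and 13 with the percentile over probes above background. Normexp moved the median difference over all genes from -0.02 to 0.09. The count was 0 with slide as a fixed block (1654 genes at an unadjusted p under 0.05), 0 within slide 1 (1183) and 0 with slide as a random block (1992, smallest adjusted p 0.0507). Within slide 1, which sets the 3 prepubertal arrays against mature array 1 alone, as the fixed block in effect does, the median of the 9 Vmn1r genes was -1.73. Single arrays moved the count: it was 277 without mature array 1, which shared a slide with the prepubertal arrays, 8 without prepubertal array 2, 5 without climacteric array 3, 4 without climacteric array 1, and 0 without prepubertal array 1 or 3, mature array 2 or 3, or climacteric array 2. It was 0 also without the 2 arrays of lowest detection, and 0 when only these 6 arrays were fitted (2669 at an unadjusted p under 0.05). The fitted differences of the 11 called genes chosen by the rule kept their sign there. For fits to a part of the arrays and for the fixed block, the rule fixed that sign, since it took only genes whose groups did not overlap. In size the differences were 1.52 to 2.43 with all arrays, and with only the 6 arrays they are the same by construction. They were 1.39 to 2.44 without the 2 arrays, 1.33 to 2.79 with slide as a fixed block and 1.52 to 2.52 as a random block. The 2.43 is that of Lpxn, set against values at background, and is not a measured size.

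Of the 32 gene lists, 11 lay higher in prepubertal than in mature oocytes by camera's test against all other genes. None kept its call when the correlation between genes was estimated (smallest adjusted p = 0.453 with an estimated correlation), or with fry (smallest 0.284). Of 85 nuclear genes of oxidative phosphorylation, 68 had a positive difference, with a median of 0.22 (camera adjusted p = 0.000842). Of 61 genes of DNA methylation and chromatin, 46 were positive (median 0.23, adjusted p = 0.00202), and of 26 oocyte identity and maternal-effect genes, 20 were (median 0.22, adjusted p = 0.0176). Lists for DNA repair (median 0.20), cohesin (0.22), the mitochondrial ribosome (0.13), translation factors (0.12), maternal mRNA storage and decay (0.13), sperm binding and egg activation (0.11), the proteasome (0.21) and telomeres (0.16) also passed, at adjusted p between 0.0219 and 0.0379. Against 10000 random lists of the same size matched on mean expression, the medians of 4 of the 11 lists lay outside the central 95% of theirs, those of oxidative phosphorylation, the proteasome, DNA repair and chromatin, and the other lists, oocyte identity among them, lay inside it. Since random genes were drawn independently, that range can be too narrow for correlated members, and a median outside it does not by itself show a shift. Among markers of other cells, 11 of 16 leukocyte markers were negative (median -0.27, adjusted p = 0.0602) and 8 of 8 erythroid markers (median -0.22, adjusted p = 0.11), without passing. The medians of the other marker lists ran from -0.09 (oviduct) to 0.11 (endothelium).

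No member of these lists was called over all genes tested. Adjusted over the list alone, 1 member of them passed, Kdm1b, an H3K4 demethylase needed for maternal imprints, with a difference of 0.78 (SE 0.15, adjusted p = 0.0383 over the list). Of lists that did not pass, Prkaa2 of nutrient sensing (at least 4.02-fold lower, not well above background on any prepubertal array) and Cdc25a of the meiotic list (0.94, SE 0.20) also passed adjusted over the list alone, with 0 called over all genes. The members with the largest differences did not pass. They were Ndufc1 (-2.50, SE 1.61) and Cox8c in oxidative phosphorylation, Sohlh1 (1.09, SE 0.95) and Sohlh2 (-0.76, SE 0.22) among oocyte identity genes, and Kdm5a (1.27, SE 0.52) and Cbx5 (1.06, SE 0.72) among chromatin genes. The Cox8c probe was above background on 2 of 3 prepubertal and on 0 mature arrays, which bounds it at least 1.76-fold higher in prepubertal oocytes. They also included Sgo1 (0.59, SE 0.30) and Esco1 (0.58, SE 0.19) of the cohesin list, and Src (1.74, SE 1.17) and Atp2a2 (0.77, SE 0.32) of the sperm binding list. In the fixed panel, 0 of 14 oocyte genes were called with limma (smallest adjusted p 0.418), and 1 had an unadjusted p under 0.05, the meiotic kinase gene Mos (-0.45, SE 0.17). The growth factor genes Gdf9 and Bmp15 differed by 0.12 (SE 0.16) and -0.04 (SE 0.19), the cohesin gene Rec8 by -0.30 (SE 0.16) and Smc1b by 0.22 (SE 1.00).

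The list count of 11 was 0 with slide as a fixed block. The oxidative phosphorylation median was then -0.01, and also -0.01 within slide 1, which rests on the same arrays with 1 mature array among them. The list count was 0 with quantile normalization, normexp, cyclic loess or the deposited table, 2 without a filter on dim probes and 6 with the mean of a gene's probes. It was 20 without mature array 1, 7 without mature array 3, 5 without prepubertal array 1 and 2 without mature array 2.

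Climacteric oocytes were set against mature oocytes, the comparison closest to the maternal age effect of the series' title. The gene Cyth4 rose in climacteric oocytes, and no other gene was called. It encodes cytohesin 4, an exchange factor for ARF GTPases best known from blood cells. Its probe, on chromosome 15 of mm9 at 78452390 to 78452449, had a level of -2.89 ± 0.58 on the 3 climacteric arrays (SD, n = 3) and was not well above background on any mature or prepubertal array. Cyth4 was thus at least 6.18-fold higher than in mature oocytes. The fitted difference, 4.91 (SE 0.28, limma adjusted p = 0.00175), is set against values at background and is not a measured size, as are the fitted values of Cyth4 in other settings. The climacteric levels were -3.46, -2.89 and -2.31 on arrays 1 to 3. Leukocyte markers stood beside it: 13 of 16 had a positive difference (median 0.28), among them Tyrobp at 3.21 (SE 0.88), above background on 3 climacteric arrays and 1 mature array, and C1qc at 1.61 (SE 0.96). Oviduct markers (9 of 12 positive, 0.31), endothelial (7 of 9, 0.29) and erythroid ones (6 of 8, 0.21) had medians of like size. Theca and stroma markers did not (6 of 11 positive, 0.05), and cumulus and granulosa markers went the other way (8 of 21 positive, -0.19). None of the marker lists passed camera's threshold (adjusted p 0.107 for leukocytes and 0.475 to 0.946 for the others).

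Cyth4 kept its call with slide as a fixed block (4.72, adjusted p = 0.0273), and within slide 2, with 2 arrays of each age, it was at least 5.54-fold higher in climacteric oocytes. It missed the threshold with normexp (1.87, adjusted p = 0.0740) and in the deposited table (1.19, adjusted p = 0.156), where in each case 1 other gene was called as lower, and over its alternatives adjusted p ranged from 0.000539 to 0.156. A filter at all 9 arrays removed it, as did leaving out any 1 climacteric array, since it was then above background on 2 arrays. At an unadjusted p under 0.05 there were 3322 genes against 1254 by chance, and the groups did not overlap for 20.6% of genes, where chance gives 10%. The median gene differed by 0.09. The count of called genes was 9 without climacteric array 1, 0 without climacteric array 2 or 3, and 2 without mature array 3. It was also 0 within slide 2 (2613 genes at an unadjusted p under 0.05), without the 2 arrays of lowest detection (2586) and with a filter at all 9 arrays (2874). In none of these was Cyth4 tested, since it was above background on too few arrays.

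None of the 32 lists passed with camera in climacteric against mature oocytes, 5 had an unadjusted p under 0.05, and the smallest adjusted p was 0.107. With fry also 0 passed, and 5 had an unadjusted p under 0.05. The lists nearest the threshold were oxidative phosphorylation (36 of 85 positive), sperm binding and egg activation (13 of 33 positive, median -0.11) and the leukocyte markers. Adjusted over the list alone, the leukocyte markers Fcer1g (0.78, SE 0.19) and Tyrobp passed, as did Mos (-0.96, SE 0.17), the histone gene H3f3a (-0.90, SE 0.18) and the chaperonin gene Cct6a (1.04, SE 0.22), with 0 of them called over all genes. Of the 14 panel genes 0 were called, with Mos and Sirt1 (-0.47, SE 0.20) at an unadjusted p under 0.05, and Zp3, Smc1b, Sgo2a and Dnmt1 differed by -0.46 (SE 0.30), -1.07 (SE 1.00), 0.35 (SE 0.18) and -0.48 (SE 0.32). Single arrays moved the list count: it was 3 without climacteric array 1, 2 without mature array 3 and 1 without mature array 2. It was 4 with normexp, without a filter on dim probes, or with the mean of a gene's probes.

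**Figure D2:**
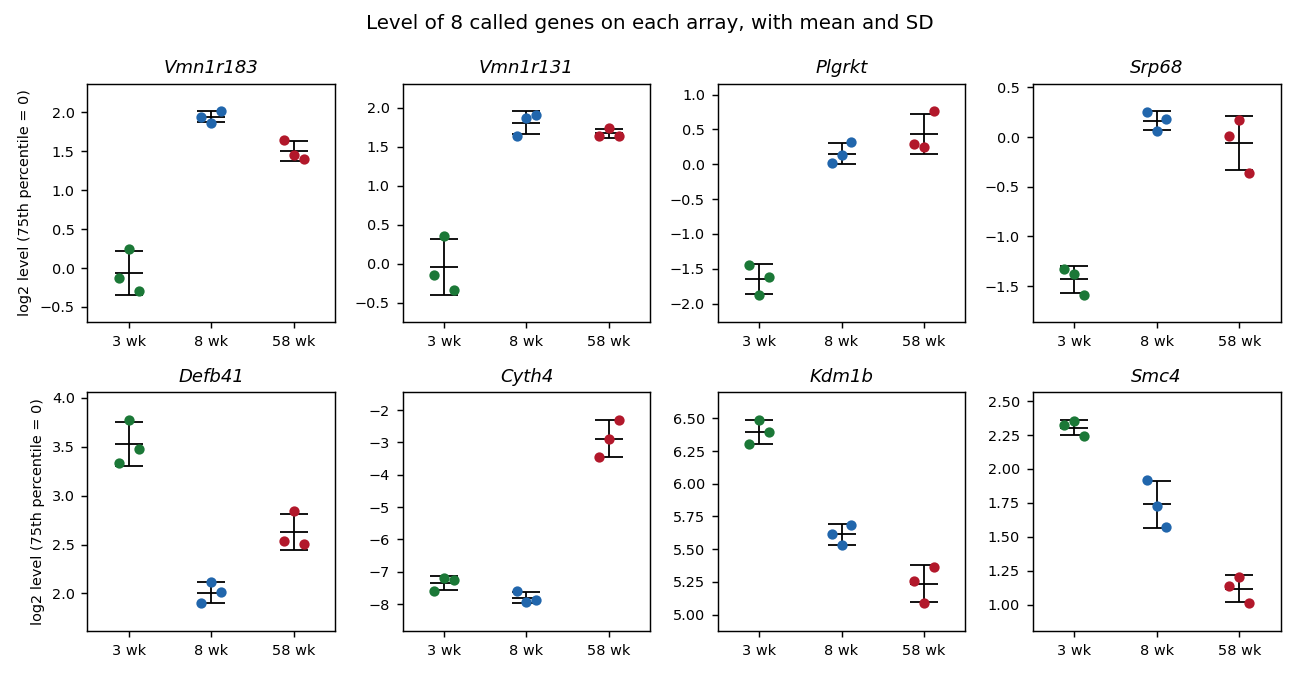
Log2 level of 8 called genes on each array (75th percentile of the array = 0) at 3, 8 and 58 weeks, with 1 point per array and bars for the mean and SD of 3 arrays. Mean Cyth4 was -2.89 in climacteric oocytes and not well above background at the other ages, while mean Vmn1r131, at -0.04 in prepubertal oocytes, was 1.81 and 1.67 in mature and climacteric ones.

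The genes changed in prepubertal and in climacteric oocytes, each against mature oocytes, had 0 genes in common, in the same or in opposite directions. Independent lists would share 0.00012 genes higher in both and 0 lower in both, so with 1 gene on one side hardly any overlap was possible. Both comparisons use the same mature arrays, so chance alone correlates them. Over genes the differences correlated at r = 0.16, where 50 simulations of unchanged groups gave a mean of 0.50. The covariance was 0.0402 against a simulated 0.0753, a difference of -0.0351. The differences had the same sign for 55.2% of genes, against a simulated 66.6%. The simulations drew each gene independently, without shifts shared by many genes on an array. Their range of r, 0.48 to 0.53, is therefore too narrow to judge these gaps, and nothing is concluded from them. The mature arrays were too few to be split, so part of any overlap would come from them.

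Climacteric and prepubertal oocytes, the oldest and the youngest group, differed in 25 genes, 19 higher and 6 lower in climacteric oocytes. Kdm1b, the H3K4 demethylase needed for maternal imprints, fell 2.23-fold, from 6.39 ± 0.09 to 5.24 ± 0.14 (SD, n = 3), and stood at 5.61 ± 0.08 in mature oocytes. Smc4, a core subunit of condensin, fell 2.28-fold, from 2.31 ± 0.06 to 1.12 ± 0.10. Prl8a2, a prolactin family gene, fell 7.95-fold and Cpox, an enzyme of haem synthesis, 7.56-fold. Trub2, a pseudouridine synthase, fell by a fitted 8.81-fold. That is set mostly against background, since its probe was above it on 1 of 3 climacteric arrays. Cyth4 was at least 5.29-fold higher, and 8 of the 9 Vmn1r genes above rose, by 2.85 to 3.88-fold.

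Among the other genes that rose, Plgrkt was 4.23-fold higher in climacteric oocytes and Eml2, a microtubule-associated protein gene, 3.67-fold. Suox (sulfite oxidase), Tnni1 (slow skeletal troponin I), Exoc7 (an exocyst subunit) and Srp68 rose 2.27, 2.28, 3.32 and 2.58-fold. The probes of Exoc7 and Srp68 lie close together on chromosome 11, at 116151283 to 116151557 and 116106502 to 116106561, and that of Eml2 on chromosome 7 at 19791721 to 19791780, before the Vmn1r block. Tmem205, Olfr1264 and Gm16697 were not well above background in prepubertal oocytes and at least 2.48, 1.29 and 1.86-fold higher in climacteric ones, and the unnamed probe A_55_P2008352 rose from below background too. Of these, Olfr1264 and A_55_P2008352 were above background on 2 of 3 climacteric arrays. The unnamed probe A_55_P2139573 fell 3.72-fold. The Trub2 probe was above background on 1 climacteric array, and a second, dim probe of the gene differed by only -0.16. The second probe of Eml2 differed by 0.55.

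These genes passed limma's test at an adjusted p between 0.00391 and 0.0476. At an adjusted p under 0.1 there were 1657 genes, 1203 of them higher and 454 lower, and the groups did not overlap for 30.4% of genes, where chance gives 10%. The 2 comparisons that use the prepubertal arrays shared 10 called genes, part of which may come from those shared arrays. By scaling, the split of 19 higher and 6 lower was 11 and 6 with quantile normalization and 12 and 12 with cyclic loess. The median difference over all genes, 0.09, became 0.21 with the percentile over probes above background. With slide as a fixed block 0 genes were called (1745 at an unadjusted p under 0.05), and 2 with slide as a random block, Cyth4 and Prl8a2; no slide held both ages. The fitted differences of the 10 called genes chosen by the rule kept their sign, with sizes of 0.86 to 4.47 and 1.14 to 4.53 in these fits, against 1.16 to 4.45 without a block. The count was 1398 without mature array 1 and 11, 7, 2, 2, 1, 1, 1 and 0 without prepubertal 2, climacteric 1, prepubertal 1, mature 3, prepubertal 3, mature 2, climacteric 3 and climacteric 2. It was 0 without the 2 arrays of lowest detection (4292 at an unadjusted p under 0.05), 302 with only the 6 arrays compared, 38 with a filter at all 9 arrays, and 4 with no filter or with each probe tested by itself.

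In the gene lists, 15 lay lower in climacteric than in prepubertal oocytes and the leukocyte markers lay higher, by camera's test. None kept its call when the correlation was estimated (smallest adjusted p = 0.379 with an estimated correlation), or with fry (smallest 0.0512). The lower lists included oxidative phosphorylation, with 64 of 85 members negative (median -0.29, camera adjusted p = 2.8e-06), and sperm binding and egg activation, with 24 of 33 negative (median -0.34, adjusted p = 0.000805). They also included the mitochondrial ribosome (49 of 77 negative, median -0.15), the cytosolic ribosome (59 of 82, median -0.12) and oocyte identity and maternal-effect genes (18 of 26, median -0.26). Of the 16 leukocyte markers 15 were positive (median 0.59, adjusted p = 0.00407). The medians of 4 of the 16 lists, those of oxidative phosphorylation, sperm binding, oocyte identity and leukocyte markers, lay outside the range of random lists matched on mean expression. Here too that range can be too narrow for lists of correlated genes.

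The other lists that passed with the preset correlation, at adjusted p of 0.0216 to 0.0495 (0.379 or higher, adjusted p with an estimated correlation), had these medians: maternal mRNA storage and decay -0.15, meiotic cell cycle -0.14, translation factors -0.14, unfolded protein response -0.20, spindle checkpoint and kinetochore -0.11, chaperones -0.10, cohesin -0.19, DNA repair -0.07, citric acid cycle -0.10 and DNA methylation and chromatin -0.08. Members of the lists with large differences, none of these called over all genes, included Nlrp5 (-0.95, SE 0.26) of the maternal-effect list, Src (-2.88, SE 1.17) of the sperm binding list, Aurka (-0.67, SE 0.20) and Cdc25a (-0.65, SE 0.20) of the meiotic list, Mrps31 (-1.22, SE 0.26) of the mitochondrial ribosome and Rps2 (-0.89, SE 0.22) of the cytosolic ribosome. Kdm1b was the list member called over all genes tested, and its list's median was small beside it.

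Adjusted over the list alone, 6 leukocyte markers were higher, among them Fcer1g (1.15, SE 0.19) and Coro1a (1.16, SE 0.24), and lower members were Kdm1b, Smc1a (-0.75, SE 0.16) of cohesin, Camk2g (-0.96, SE 0.16) of egg activation, Pdp1 (-0.75, SE 0.13) of the citric acid cycle, Dnaja1 and Dnaja2 of the chaperones (-0.67 and -0.78) and Eif2s2 (-0.88, SE 0.19) of the translation factors, with Eif2b5 higher (1.09, SE 0.23). Of the panel, 0 of 14 genes were called with limma, and Rec8 (0.39, SE 0.16), Mos (-0.50, SE 0.17) and Dnmt1 (-0.97, SE 0.32) had an unadjusted p under 0.05. Gdf9, Bmp15 and Zp3 differed by 0.10 (SE 0.16), -0.39 (SE 0.19) and -0.23 (SE 0.30).

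With slide as a fixed block the list count of 16 became 0, the oxidative phosphorylation median was 0.04 and that of the leukocyte markers 0.27. It was 3 with quantile normalization or cyclic loess, 4 in the deposited table and 8 with the percentile over probes above background. It was 7 without climacteric array 3, 9 without prepubertal array 2 and 6 without the 2 arrays of lowest detection.

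**Figure D3:**
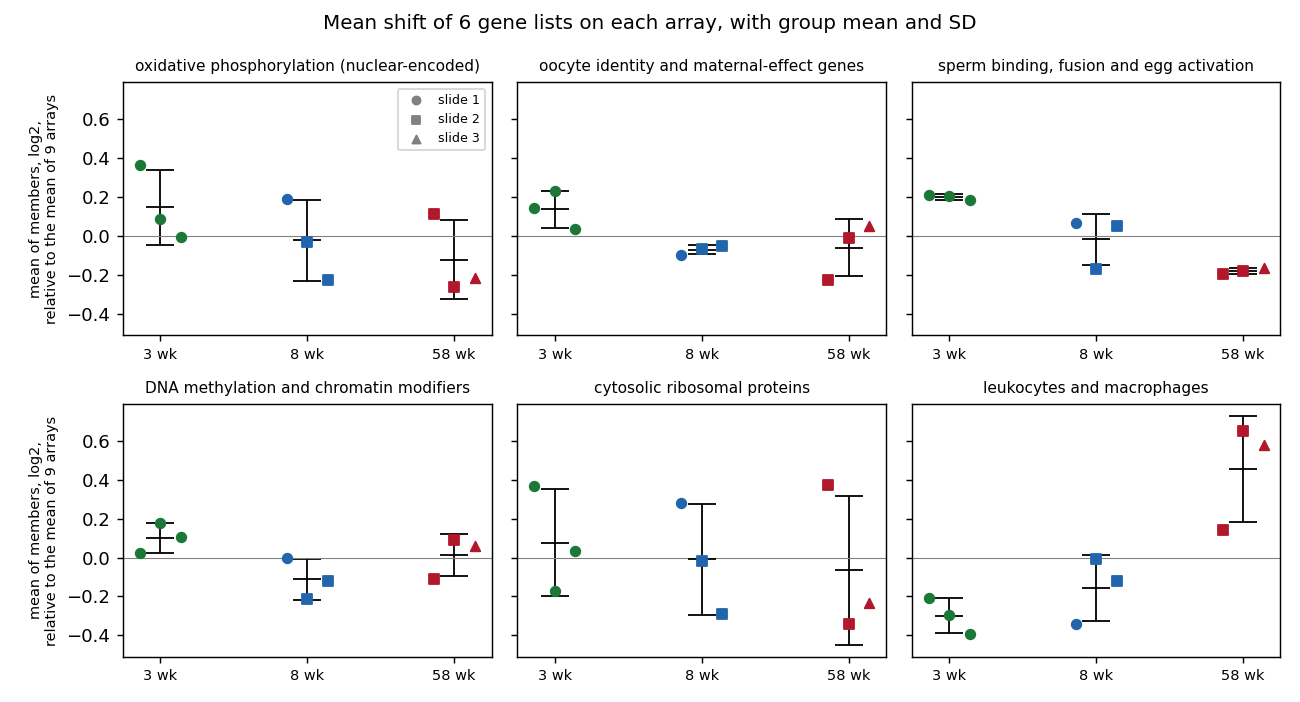
Mean of the members of 6 gene lists on each array (log2, relative to the mean of the 9 arrays) at 3, 8 and 58 weeks, with 1 point per array shaped by slide and bars for the mean and SD of 3 arrays. The leukocyte markers lie between -0.39 and -0.21 on the prepubertal and between 0.14 and 0.65 on the climacteric arrays, while the cytosolic ribosome varies within each age, from -0.34 to 0.37 among climacteric arrays.

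Over the 3 ages together, 12 genes changed by limma's F test (adjusted p 0.00286 to 0.0439), against 4919 genes at an unadjusted p under 0.05. They were Cyth4, Prl8a2, Plgrkt and 9 Vmn1r genes. Prl8a2 stood at 3.28, 2.48 and 0.29 in prepubertal, mature and climacteric oocytes, and Plgrkt at -1.65, 0.15 and 0.44. Vmn1r131 stood at -0.04, 1.81 and 1.67. The count was 640 without mature array 1, 7 without climacteric array 1, 5 without prepubertal array 2, 1 without prepubertal array 1 or 3 or mature array 2 or 3, and 0 without climacteric array 2 or 3. It was 0 with slide as a fixed block (2282 at an unadjusted p under 0.05), 2 with slide as a random block, 2 without a filter on dim probes, and 4 or 6 with the mean of a gene's probes or each probe by itself.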

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

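Cyclic loess, slide as a random block, the fits within a slide and the fit without the 2 arrays of lowest detection were chosen only after the data were seen, and all other alternatives beforehand. All values in this part are counts of called genes or lists, or list medians in log2, and where no reason is given the cause of a change was not tested. Of 548 values of 22 called gene results over the alternatives, 254 stayed past the threshold, 294 did not and 0 changed sign. Where arrays were only left out, the sign of a probe was fixed in advance, since the rule took genes whose groups did not overlap. Of 3143 values of 127 uncalled results, 6 passed the threshold and 68 changed sign. Calls shared between the 2 comparisons with mature oocytes were 0 in all settings run. Scan date was not run as a block, since all arrays shared 1 scan day, and signal over background limits what dim probes can show.

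For prepubertal against mature, the 14 genes became 0 with only the 6 arrays compared, 0 with slide as a fixed block, 0 with slide as a random block, 0 within slide 1 and 0 without the 2 arrays of lowest detection. The last leaves fewer arrays, as do the fits within a slide and the fit of 6. By limma, unadjusted p was under 0.05 for 2669, 1654, 1992, 1183 and 2043 genes there. Leaving out each array in turn gave 0 to 277. For climacteric against mature, the 1 gene became 0 with a filter at all 9 arrays (2874 at an unadjusted p under 0.05), 0 within slide 2 (2613) and 0 without the 2 arrays (2586), and 0 to 9 without each array. The filter at all 9 arrays removed Cyth4, which was above background on 3 arrays. Within slide 2, without the 2 arrays and without any 1 climacteric array, it was above background on too few arrays to be tested. A count of 0 there is thus not a failed test of Cyth4.

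For climacteric against prepubertal, the 25 genes became 4 with no filter on dim probes, 38 with the filter at all 9 arrays, 4 with each probe by itself, 302 with only the 6 arrays compared, 0 with slide as a fixed block (1745), 2 with slide as a random block and 0 without the 2 arrays (4292). Without each array the count was 0 to 1398. Across the 3 ages, the 12 genes became 2 with no filter, 4 with the mean of a gene's probes, 6 with each probe by itself, 0 with slide as a fixed block (2282), 2 with slide as a random block and 0 without the 2 arrays (3188), and 0 to 640 without each array.

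With the replicate number as a block, 0 genes were called for prepubertal against mature (2757 at an unadjusted p under 0.05), 1 for climacteric against prepubertal and 1 across the 3 ages. Of the 9 pairs of arrays with the same number, 7 had a positive correlation of their deviations and 3 one over 0.1 (range -0.0852 to 0.213), and not every array correlated best with its own number. Pairing needed every correlation over 0.1, so the numbers were not taken as pairs, though a part in common is not excluded.

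The 11 lists of prepubertal against mature became 0 with normexp, 0 with quantile normalization, 0 with cyclic loess, 0 in the deposited table, 2 with no filter, 6 with the mean of a gene's probes, 0 with slide as a fixed block, 2 within slide 1, 0 with an estimated correlation and 0 with fry, and 2 to 20 without each array. For climacteric against mature, 0 lists became 4 with normexp, 4 with no filter and 4 with the mean of a gene's probes, and 0 to 3 without each array. The 16 lists of climacteric against prepubertal became 3 with quantile normalization, 8 with the percentile over probes above background, 4 in the deposited table, 0 with slide as a fixed block, 3 with cyclic loess, 6 without the 2 arrays, 0 with an estimated correlation and 0 with fry, and 7 to 19 without each array.

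Camera's direction turned for the lists named next, none of them then past the threshold (adjusted p 0.0794 to 0.984), and the 2 lists lower within slide 1 were others. For prepubertal against mature the medians with slide as a fixed block and within slide 1 were -0.0102 and -0.0125 for oxidative phosphorylation, -0.0010 and 0.00058 for the mitochondrial ribosome, 0.032 and 0.025 for the proteasome, and -0.0085 and 0.011 for translation factors, and the blocked median was -0.019 for sperm binding. For climacteric against prepubertal the blocked medians were 0.037 for oxidative phosphorylation, 0.059 for the mitochondrial ribosome, 0.37 for the cytosolic ribosome, 0.16 for translation factors, -0.011 for chromatin and 0.10 for the unfolded protein response.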

Other observations

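The tests of slide for the Vmn1r genes and for Cyth4 and the test of leukocyte markers were chosen only after their result was seen. The other tests were chosen before their own values were seen. Those on the Vmn1r genes and on the shifted lists were still written for patterns already seen in these data. How 4 of the values are read, those on alike probes, on neighbouring genes and on slide for the Vmn1r genes and Cyth4, was also settled after they were seen.

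Lists of glycolysis, cholesterol, apoptosis and antioxidant genes did not pass camera's threshold between climacteric and prepubertal oocytes (medians 0.17, 0.20, 0.05 and 0.05; adjusted p 0.611, 0.823, 0.917 and 0.772). Nor did histones (median 0.12, adjusted p = 0.843), nutrient sensing (-0.21, 0.0615), autophagy (-0.17, 0.0641), mitochondrial dynamics (-0.08, 0.0641) or oocyte-biased multigene families (-0.01, 0.0599). Within autophagy, 2 members were higher and 5 lower adjusted over the list alone, among them Uvrag (-0.87, SE 0.21) and Atg14 (-0.70, SE 0.15), with 0 called over all genes. The histone genes H2bc3 (1.07, SE 0.21) and H3f3a (-0.84, SE 0.18) went opposite ways, each passing adjusted over the list alone. In this comparison camera's direction opposed the sign of the median for 6 of the 32 lists, histones, glycolysis, cholesterol, apoptosis, antioxidant and telomere genes, each lower by camera with a positive median, and the mean opposed the median for 3. Camera opposed the median for 15 lists for climacteric against mature and 3 for prepubertal against mature, and the mean opposed it for 7 and 5. Camera sets a list against all other genes, whose median was 0.09, and the cause of the difference in sign was not tested.

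Markers of other cells were measured in the same way. For climacteric against prepubertal oocytes, 10 of 12 oviduct markers (median 0.50, adjusted p = 0.109) and 7 of 8 erythroid markers (median 0.45, adjusted p = 0.103) were positive, without passing. Cumulus and granulosa markers had a median of -0.24 (adjusted p = 0.13), theca and stroma 0.27 (0.843) and endothelium 0.20 (0.917). Dim genes in general rose as well, by a median of 0.32 in the dimmest of 10 bins by mean signal. These marker lists were not set against genes of like signal. Adjusted over the list alone, Cyp11a1 of the granulosa list (3.03, SE 0.58), Col1a2 of the stroma list (1.17, SE 0.24), and Hbb-bt (0.85, SE 0.21) and Hba-a1 (0.71, SE 0.22) of the erythroid list were higher, with 0 called over all genes.

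The 9 Vmn1r genes lower in prepubertal oocytes lie in 1 block of chromosome 7. A slide difference stays open: their median was -1.73 within slide 1 against -1.92 over all arrays, but slide 1 holds a single mature array, which also helped to select these genes. One or a few transcripts read by near-identical probes stays open: 8 of the 9 have an alike called probe, and the only uncalled gene with an alike probe differed by 0.67, which met the bound set beforehand against it but is a single gene without a spread, and the median of -0.17 of the 88 uncalled genes with less alike probes decides nothing, since they were taken for not being called. A genetic difference between the mice also stays open. Per the labels all females were B6C3F1 hybrids of the same parent strains, which leaves less room for such a difference. The 11 pairs of neighbouring genes among the 200 uncalled genes of smallest p met the bound set against it. Yet they lie inside the 8 to 25 pairs of random draws. The neighbouring calls Srp68 and Exoc7, and Eml2 and the Vmn1r block, were noticed before that test was written. An effect of age on these genes is a further open explanation and was not tested.

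The gene lists shifted between climacteric and prepubertal oocytes could follow a trend with signal intensity. The median difference was 0.32 in the dimmest of 10 bins of genes by mean signal and -0.17 in the next to brightest, and the medians of only 4 of the 16 lists lay outside random lists matched on mean expression, those of oxidative phosphorylation, oocyte identity, sperm binding and leukocyte markers. That is what such a trend would give for the others. The range can be too narrow for lists of correlated genes, so the 4 are not shown to move beyond the trend. A slide difference cannot be told apart from age here: 0 of 16 lists stayed past the threshold with slide as a fixed block, 10 kept their direction, and no slide held both ages. Age itself stays open and untested for all 16 lists, since a median inside the range does not exclude it.

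For Cyth4, a slide difference as the whole cause is argued against by the 2 climacteric and 2 mature arrays of slide 2, where the difference was at least 2.47 in log2, a lower bound since the probe was not well above background on the mature arrays. These arrays also helped to select Cyth4, so the sign of that difference was fixed in advance and only its size bears on the question. RNA of leukocytes may be a source: the markers' median against mature oocytes was 0.28, with an SD of 0.88 and a range from -0.24 to 3.21, too wide to decide. Of the 16 markers 14 were well above background on all arrays, prepubertal ones included, and the brightest, Itgam, stood at 6.63, 6.60 and 6.71 in prepubertal, mature and climacteric oocytes. Removal of cumulus cells, as the labels describe, would not by itself remove blood cells. An effect of age was not tested.

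Other splits of the arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For genes, 1 of 10 splits gave as many for prepubertal against mature (14, highest other 1), 1 of 10 for climacteric against mature (1, highest other 0) and 1 of 10 for climacteric against prepubertal (25, highest other 1). For lists, 5 of 10 gave as many for prepubertal against mature (11, highest other 15), 10 of 10 for climacteric against mature (0, highest other 13) and 1 of 10 for climacteric against prepubertal (16, highest other 9). The 3 splits that put mature array 1 with 2 prepubertal arrays, as slide 1 does, gave 15, 12 and 11 lists, and with slide as a fixed block 0 lists passed. Across the 3 ages, the real grouping was set among 100, the others drawn at random, and it alone gave 12 genes (highest other 8). That share is under 0.05, but the draws ignore slide, which largely follows age. With slide as a fixed block the count of genes across ages was 0. Of the 12 genes 9 are Vmn1r genes, most with alike probes, so they are not separate results. The draws therefore do not show that age was the cause of the count.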
